A study of Mus musculus with 12 samples.

How the data were processed

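RNA sequencing was analysed from 12 libraries of E14 cells, a mouse embryonic stem cell (ESC) line. Wild-type (WT) cells and cells with a knockdown (KD) of circKat6b-e2, a circular RNA named after exon 2 of Kat6b, were sampled as undifferentiated ESCs and as embryoid bodies (EBs) at day 6. EBs are aggregates in which ESCs leave the pluripotent state and form cells of several lineages. The sample titles mark the KD as made with an shRNA. The labels do not state whether WT cells carried a control shRNA, or whether KD cells were a clone or a pool, so each KD minus WT value also covers any other difference between these cell populations. Each of the 4 groups held 3 libraries, and the series states that these were biological replicates. Per the labels' protocols, ESCs were grown on gelatin with LIF, a MEK inhibitor and a GSK3 inhibitor, which together hold the naive state. Per the labels' protocols, mRNA was selected with poly-T beads, and paired reads were sequenced from libraries made with a NEBNext Ultra kit. A poly-T selection does not retain circular RNA, so the knocked-down molecule itself was not measured here and only the gene counts of its host gene Kat6b were.

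The deposited values were raw counts per gene, in 1 table per stage. Per the submitters' processing notes, reads were aligned with HISAT2 version 2.1.0 to mm10 and counted with featureCounts version 2.0.3, and DESeq2 version 1.18.1 was named. Per the file headers, the deposited counts were made with the Ensembl release 90 gene annotation of GRCm38, for paired reads with both ends mapped and with chimeric pairs left out. The header named no strand option, so reads of a gene and of an antisense or overlapping partner cannot be told apart. It also named no option to count pairs, and low counts were mostly even: between 61.7% and 68.7% of counts from 1 to 10 per library, against 48.0% to 51.6% of those from 101 to 1000. Each mate of a pair therefore entered the deposited counts on its own, which overstates the number of fragments by up to about a factor of 2. Both tables held the same 52636 genes, of which 52403 identifiers were matched to a symbol, 233 were not, and 21273 had no count in any library. How multiply aligned reads were treated was not given in the sources used here, so counts of near-identical genes are uncertain.

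Total counts ranged from 25.4 to 37.8 M per library, and 20021 to 23548 genes had a count. Replicates were compared before they were averaged, and no pair held identical values. The chi-square per gene lay between 4.96 and 9.57 for replicate pairs without ESC WT replicate 2, and at 60.88 and 61.67 for the pairs with it. All libraries were retained as separate replicates. SDs and SEs cover the spread between these libraries. The intervals of odds ratios and of the bootstrap cover the spread over genes, and a Poisson bound covers counting error alone. PCR copies were not told apart from independent molecules.

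KD was compared with WT within each stage by edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) with TMM normalization, the filterByExpr filter (a minimum count of 10 and a minimum total of 15), robust dispersion estimates and no covariate. The difference of the KD effect between stages, and EBs against ESCs in WT and in KD cells, came from a single fit of all 12 libraries in 4 groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are KD minus WT or EB minus ESC. Their standard error (SE) is the absolute log2 fold change divided by the square root of F, and CPM are counts scaled by the normalised library size, in the usual unit, as mean ± SD with n = 3 unless stated. CPM of KD against WT within a stage used the normalization of that stage alone. CPM given for the difference between stages or for EBs against ESCs used that of all 12 libraries, so levels of the same group differ.

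The design, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. The 31 lists were the targeted gene and MORF complex (the histone acetyltransferase complex of KAT6A and KAT6B), naive pluripotency, core pluripotency, formative and primed pluripotency, 2-cell-like state, primitive streak, mesoderm, cardiac muscle, haemato-endothelial, definitive endoderm and gut, extraembryonic endoderm, neuroectoderm, surface ectoderm and epithelium, trophoblast, germline, Hox, fibroblast, p53 targets, cell cycle, interferon response, WNT targets, LIF and STAT3 targets, ERK targets, TGF-beta, NODAL and BMP targets, integrated stress response, immediate early and heat shock, hypoxia and glycolysis, imprinted genes, mitochondrially encoded mRNAs, ribosomal proteins and replication-dependent histones. Some genes stood in 2 lists, such as Gata4 in mesoderm and extraembryonic endoderm. Each list was tested with camera (limma 3.58.1, preset correlation 0.01), which compares a list with all other tested genes, and adjusted over the 31 lists of a comparison. An estimated correlation and fry were alternatives.

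The genes named were Kat6b and the MORF complex members, and the 6 largest rises and falls per stage among called genes with a mean logCPM of at least 2, no overlap between the KD and WT libraries and a symbol that is not a gene model. Up to 2 members of each list called by camera and 1 of every other list were added by smallest adjusted p. For the difference between stages the rule took the 6 largest per direction, and for EBs against ESCs 1 member per list. Genes outside this rule are said in the text to have been chosen after their values were seen.

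The 2 sets of up to 500 genes each, with the largest rise and the largest fall from ESCs to EBs averaged over WT and KD, were tested for the KD effect within each stage. Calls shared between stages were tested with Fisher's exact test per direction, and the per-stage fits share no library. The alternatives were median-of-ratios factors, library size only, no filter, a mean CPM of at least 1, DESeq2 1.42.0, the replicate number as a block, all 12 libraries in 1 fit, a log2 fold change of at least 1, a set size of 200, an estimated correlation, fry and each library left out. Halved counts and limma voom with sample quality weights were chosen after seeing the data. DESeq2 adjusted p-values that were missing stayed missing.

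The tests were checked on simulated counts with 200 changed genes per comparison, as many rises as falls, and each gene drawn on its own. The real EB comparison called 9667 of 17355 genes. The simulations therefore do not check the scaling under so broad a change, or camera on genes that vary together. Of the genes changed 1.5-fold, 2-fold and 4-fold, 36.4%, 65.7% and 90.5% were recovered in the simulation of the ESC comparison over 16081 genes, with 8 false calls among 134. In that of the EB comparison over 17355 genes these were 64.6%, 76.9% and 93.7%, with 10 false calls among 161. In that of the difference between stages over 18975 genes they were 20.0%, 44.6% and 60.9%, with 1 false call among 82. Of the gene lists, none of which was set to change as a list, camera called 2 in the simulated ESC comparison, 0 in the EB comparison and 1 in the difference. The changed genes were drawn at random from all genes and may lie in these lists, so these are not counts of false calls alone.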

Results

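The data compare WT and circKat6b-e2 KD cells as ESCs and as day 6 EBs, with 3 libraries in each of the 4 groups. Total counts were 37.8, 31.4 and 29.0 M for the WT ESC libraries, 25.4, 28.3 and 30.1 M for the KD ESC libraries, 32.3, 31.1 and 35.0 M for the WT EB libraries, and 32.1, 30.3 and 32.7 M for the KD EB libraries. Stage separated the 12 libraries on the first principal component, which held 83.0% of the variance. Within EBs, WT and KD libraries were separated on a first component with 69.7% of the variance. Within ESCs the first component held 41.9% and set ESC WT replicate 2 (−73.0) apart from the other libraries, whose values ran from −6.11 to 30.2.

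**Figure D1:**
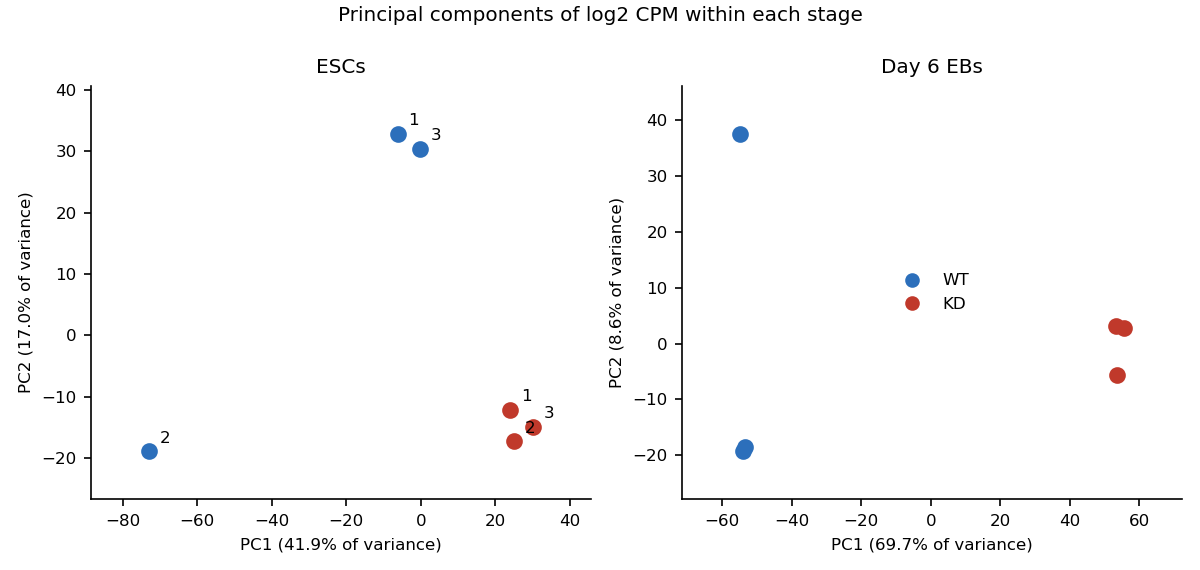
Principal components of log2 CPM within ESCs and within day 6 EBs, 1 point per library, WT in blue and KD in red, with the percent of variance on each axis and replicate numbers beside the ESC points. WT and KD EBs lie at opposite ends of the first component, while ESC WT replicate 2 lies apart from the other 5 ESC libraries.

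Kat6b, the host gene of the targeted circular RNA on chromosome 14, was higher in KD EBs, at 70.6 ± 1.46 CPM against 35.8 ± 1.14 CPM in WT EBs (log2 fold change 0.98, SE 0.06, edgeR adjusted p = 2.57e-15, higher in each of the 3 KD libraries). In ESCs it stood at 88.8 ± 3.65 CPM in KD and 67.0 ± 9.87 CPM in WT cells, a log2 fold change of 0.41 (SE 0.10) that missed the threshold (edgeR adjusted p = 0.0893). The ESC call was made in some settings, such as DESeq2 (adjusted p = 0.0283), and without ESC WT replicate 2 (edgeR adjusted p = 0.00208). These counts come from linear host transcripts and check nothing about the level of the circular RNA. Other members of the MORF complex list also rose in EBs on the log2 scale. These were Brpf3 (0.97, SE 0.05), Meaf6 (0.50, SE 0.08), Kat6a (0.48, SE 0.04) and Brd1 (0.15, SE 0.04). Their edgeR adjusted p ran from 1.13e-17 to 0.00298, and Brpf1, Ing4 and Ing5 did not pass. Brd1 lost its call without EB KD replicate 2 and in the fit of all 12 libraries. The list of 8 had 5 members higher and 0 lower (camera adjusted p = 0.00305), a call lost with an estimated correlation (adjusted p = 0.111). In ESCs 0 of the 8 members passed over all genes and 2 adjusted over the list alone (median 0.23, camera adjusted p = 0.180).

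In undifferentiated ESCs, which address the effect of the KD on self-renewing cells, transcripts of the 2-cell-like state fell, as did the imprinted growth regulator Phlda2. Gm21761 was at 1.24 ± 0.22 CPM in KD and 9.92 ± 2.25 CPM in WT cells (log2 fold change −3.00, SE 0.25, edgeR adjusted p = 6.12e-04), and Zscan4c, a marker of the rare 2-cell-like cells of ESC cultures, at 0.157 ± 0.0705 and 1.93 ± 0.228 CPM (−3.57, SE 0.53, adjusted p = 0.0196). Of the 8 tested members of this list, 2 fell over all genes and 7 adjusted over the list alone, with a median log2 fold change of −3.00 (camera adjusted p = 2.83e-17, and adjusted p = 0.0244 with an estimated correlation). Members of the Zscan4 family are near-identical copies, so reads may have been split among them. The call of the list held in each of the settings tried, while Zscan4c was called in only 2 of the 6 fits with 1 ESC library left out (adjusted p from 0.0659 to 0.142 in the others).

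Among called genes with a mean logCPM of at least 2 and a symbol that is not a gene model, the largest falls in KD ESCs were those of Phlda2 (log2 fold change −2.08, SE 0.17), Slc22a18 (−2.004, SE 0.21), Smtnl1 (−1.99, SE 0.19), the cadherin Celsr2 (−1.94, SE 0.18), the metallothionein Mt3 (−1.54, SE 0.23) and Lars2, the mitochondrial leucyl-tRNA synthetase (−1.44, SE 0.13). Their edgeR adjusted p ran from 6.12e-04 for Phlda2 to 0.0196 for Mt3. Phlda2 and Slc22a18 are imprinted neighbours on distal chromosome 7, and Phlda2 went from 56.5 ± 9.21 to 13.3 ± 2.91 CPM. The largest rises under the same rule were those of the X-linked Xlr3a (1.80, SE 0.20), which belongs to a family of similar copies, the neurofilament gene Nefm (1.42, SE 0.22), the lymphangiogenic factor Vegfc (1.06, SE 0.18), Pou2f3 (1.00, SE 0.16), the WNT target Sp5 (0.93, SE 0.18) and Myc (0.84, SE 0.16). Their edgeR adjusted p ran from 0.00374 for Xlr3a to 0.0454 for Sp5. Of the 6 fits with 1 ESC library left out, Xlr3a was called in 5 and Mt3, Nefm, Vegfc, Pou2f3, Sp5 and Myc in 2 each. Vegfc, Pou2f3, Sp5 and Myc also lost the call with library size only (edgeR adjusted p from 0.0574 to 0.0910).

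Mitochondrially encoded mRNAs were higher and ribosomal protein mRNAs lower in KD ESCs by the list test. Of the 12 mitochondrial mRNAs 1 rose, mt-Nd2 (log2 fold change 0.54, SE 0.10, edgeR adjusted p = 0.0380), and 5 adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.0102, adjusted p = 0.703 with an estimated correlation, and adjusted p = 0.116 without ESC WT replicate 1). None of the 89 ribosomal protein mRNAs passed (0 adjusted over the list alone), while their median was −0.30 (camera adjusted p = 2.27e-11, and adjusted p = 0.703 with an estimated correlation). Without ESC WT replicate 2, the library apart from the rest, that median was −0.12, with the call retained. Other lists had members past the threshold. The germ-cell gene Stra8 (−0.81, SE 0.14), the cell-cycle inhibitor Cdkn2a (−0.95, SE 0.16), the cardiac light chain Myl4 (−1.02, SE 0.20), the endocytic receptor subunit Amn (−1.04, SE 0.13), the NODAL inhibitor Lefty2 (−0.69, SE 0.11) and Krt19 (−0.74, SE 0.12) fell on the log2 scale, and the DNA methyltransferase Dnmt3b rose (0.52, SE 0.09), with edgeR adjusted p from 0.00791 to 0.0488. With 1 ESC library left out, Amn and Krt19 were called in 3 of 6 fits and the others, like mt-Nd2, in 2, and all but Amn and mt-Nd2 lost the call with library size only (edgeR adjusted p from 0.0608 to 0.109). Naive pluripotency had no member past the threshold over all genes, 8 higher and 1 lower adjusted over the list alone, a median of 0.13 and a camera adjusted p of 0.0920. It was called without ESC WT replicate 2 (camera adjusted p = 0.00716), though with a smaller median of 0.07, with DESeq2 (0.0151), without a filter (0.0380) and with library size only (0.0318), of a range from 0.00716 to 0.703. Surface ectoderm (camera adjusted p = 0.0920) was called without ESC KD replicate 3 (0.0336). Surface ectoderm (0.0437) and replication-dependent histones (0.0318, against 0.223) were also called with library size only. Imprinted genes (4 lower of 22) had a positive median (0.19) with a negative mean (−0.17) and test direction. Median, mean and test also differed in sign for primitive streak, neuroectoderm, trophoblast, p53 targets, cell cycle, TGF-beta, NODAL and BMP targets, and hypoxia and glycolysis, none of them called.

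By edgeR, 97 of 16081 tested genes changed in ESCs, 27 higher and 70 lower, of which 33 (8 higher, 25 lower) changed by a log2 fold change of at least 1, and 3447 had an unadjusted p under 0.05. This count rested on the libraries included. It was 23 without ESC WT replicate 1, 1557 without replicate 2, 296 without replicate 3, and 10, 8 and 8 without KD replicates 1, 2 and 3, of which 19, 97, 91, 10, 8 and 7 were among the 97. In each of these 6 fits the same 7 genes were called, among them Celsr2, Gm21761, Lars2, Phlda2, Slc22a18 and Smtnl1 of the genes named above. With DESeq2 the count was 909, with library size only 36. The share of higher genes also moved, from 27.8% to 48.5% (969 higher, 1030 lower) in the fit of all 12 libraries, 40.1% (624 and 933) without ESC WT replicate 2, 39.0% (690 and 1079) without a filter and 12.5% (1 and 7) without ESC KD replicate 3.

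Day 6 EBs address the effect of the KD on differentiation, and there naive pluripotency transcripts were higher in KD cells. Of the 20 naive markers 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 1.44 (camera adjusted p = 5.52e-09, and adjusted p = 0.0273 with an estimated correlation). Esrrb stood at 42.0 ± 5.30 CPM in KD and 6.73 ± 0.943 CPM in WT EBs (2.64, SE 0.11, edgeR adjusted p = 3.34e-18), and Klf2 at 28.8 ± 0.914 and 4.72 ± 0.610 CPM (2.61, SE 0.11, edgeR adjusted p = 5.49e-19). Of the 16 core pluripotency genes 9 rose and 6 fell (camera adjusted p = 0.294), among the latter Trim71 (−1.23, SE 0.03, edgeR adjusted p = 7.60e-24). Of the 17 formative and primed genes 5 rose and 9 fell (camera adjusted p = 0.272), among the latter Pou3f1 (−1.93, SE 0.10, edgeR adjusted p = 5.22e-17). Of the 6 tested 2-cell-like genes 2 rose and 0 fell (camera adjusted p = 0.605). Zscan4a, 1 of these, lost its call without EB WT replicate 1 or EB KD replicate 1.

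Mesoderm, haemato-endothelial, fibroblast and Hox transcripts rose in KD EBs. Of 22 mesoderm genes 13 rose and 4 fell (median 0.72, camera adjusted p = 2.12e-10, and adjusted p = 0.0274 with an estimated correlation). Among the rises was Hand2 (2.19, SE 0.05, edgeR adjusted p = 1.36e-25), which encodes a transcription factor of lateral and cardiac mesoderm. Of 14 haemato-endothelial genes 10 rose and 2 fell (median 1.68, camera adjusted p = 4.73e-06, and adjusted p = 0.0315 with an estimated correlation), among them the VEGF receptor genes Flt1 (1.22, SE 0.04) and Kdr (1.04, SE 0.06). Of 16 fibroblast genes 10 rose and 4 fell (median 0.64, camera adjusted p = 6.54e-19, and adjusted p = 0.0104 with an estimated correlation), among them the matrix protein gene Postn (4.51, SE 0.06) and smooth muscle actin Acta2 (1.90, SE 0.03). Of 38 Hox genes 29 rose and 3 fell (median 1.87, camera adjusted p = 6.87e-19, and adjusted p = 0.0104 with an estimated correlation), among them Hoxa10 (3.84, SE 0.11) and Hoxa9 (2.87, SE 0.09). Hox clusters hold antisense transcripts that counts without strand do not separate. Extraembryonic endoderm had 13 of 22 genes higher and 4 lower (median 0.32, camera adjusted p = 1.55e-05, and adjusted p = 0.0315 with an estimated correlation), with the endocytic adaptor Dab2 (1.51, SE 0.04) and the yolk sac transport protein gene Ttr (1.86, SE 0.04) among the rises.

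Among called EB genes with a mean logCPM of at least 2, collagen Col3a1 rose most, while some genes below that level had larger fold changes. It went from 11.3 ± 2.504 to 828 ± 16.9 CPM (log2 fold change 6.19, SE 0.15, edgeR adjusted p = 5.94e-06). It was followed by the endothelial ligand Angpt1 (5.85, SE 0.24), the matrix proteoglycan Lum (5.81, SE 0.14), Hoxc11 (5.70, SE 0.25), Postn (above) and Tril (4.47, SE 0.21). The largest falls under the same rule were those of the water channel Aqp1 (−4.80, SE 0.26), the neural crest factor Sox10 (−4.13, SE 0.37), Oas3 (−3.47, SE 0.23), the imprinted cell-cycle inhibitor Cdkn1c (−3.45, SE 0.05), Wnt9b (−3.44, SE 0.14) and Ctse (−3.35, SE 0.23). Cdkn1c, on chromosome 7 from 143458339 to 143461050 in GRCm38, went from 163 ± 2.38 to 14.9 ± 0.573 CPM (edgeR adjusted p = 2.49e-30).

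**Figure D2:**
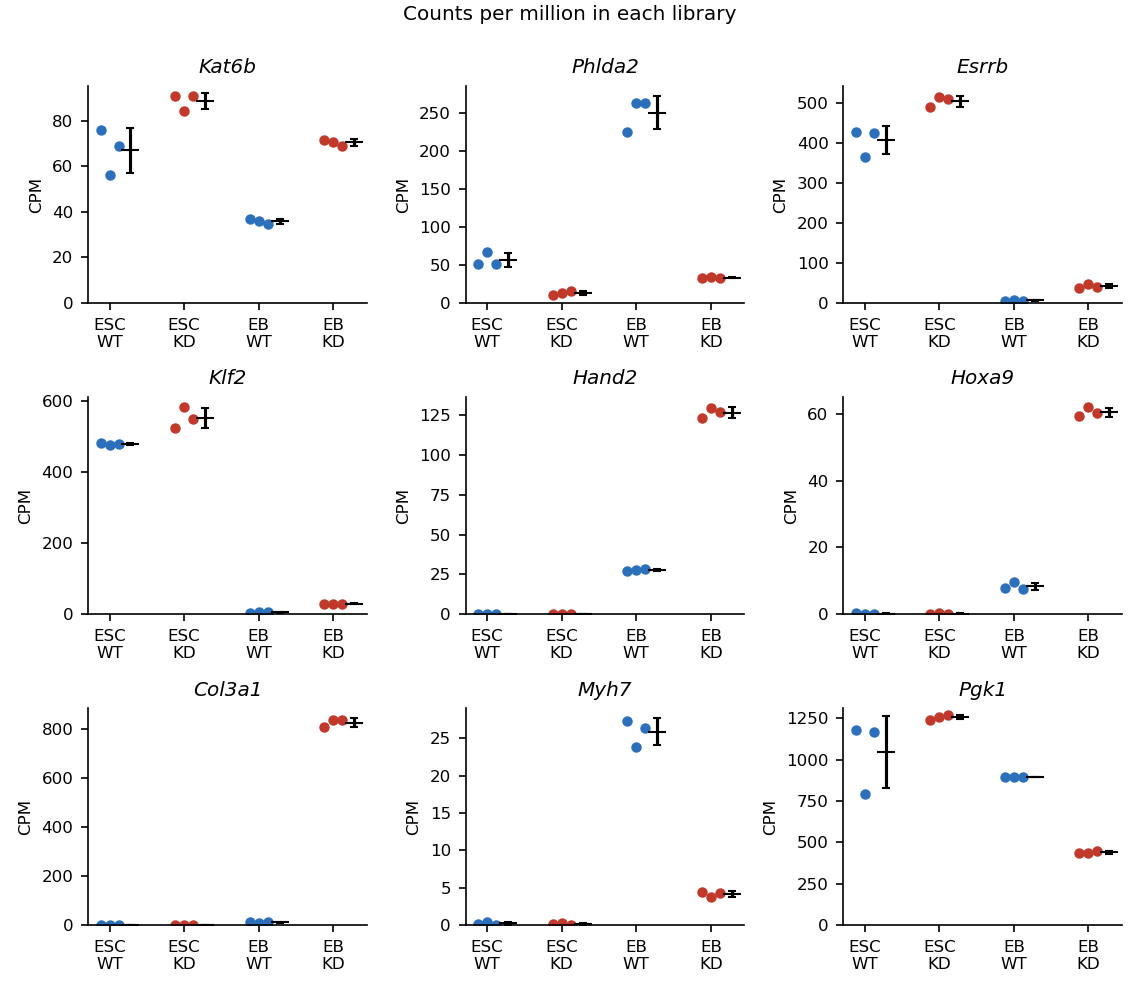
CPM of 9 genes in each of the 12 libraries, with each stage normalised on its own, WT in blue and KD in red. Points are libraries, and the black bar is the mean ± SD of 3. Esrrb, Klf2, Hand2, Hoxa9 and Col3a1 were higher, and Phlda2, Myh7 and Pgk1 lower, in each KD EB library than in each WT EB library.

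Genes of hypoxia and glycolysis fell in KD EBs. Of the 23 genes 19 fell and 1 rose (median −0.65, camera adjusted p = 2.88e-15, and adjusted p = 0.0274 with an estimated correlation), among them the glycolytic enzyme genes Pgk1 (−1.02, SE 0.03, edgeR adjusted p = 1.73e-23) and Ldha (−0.87, SE 0.03, edgeR adjusted p = 2.17e-22). Imprinted genes moved both ways, with 15 of 25 higher and 5 lower (median 0.68, camera adjusted p = 2.40e-05, and adjusted p = 0.0333 with an estimated correlation). Mest rose from 803 ± 14.6 to 2803 ± 110 CPM (1.80, SE 0.03), while Cdkn1c fell as given above.

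The calls of 6 further EB lists were lost with an estimated correlation. Cardiac muscle had 9 of 15 genes lower and 3 higher (camera adjusted p = 1.04e-04, and adjusted p = 0.0866 with an estimated correlation), among the falls the myosin genes Myh7 (−2.64, SE 0.11) and Myl3 (−2.04, SE 0.10). The p53 targets had 13 of 22 lower and 4 higher (camera adjusted p = 1.04e-04, and adjusted p = 0.0866 with an estimated correlation), among the falls Btg2 (−1.36, SE 0.04) and Zmat3 (−0.79, SE 0.04). Cell cycle genes, of which 15 of 32 were lower and 8 higher, gave a camera adjusted p of 0.00110 and an adjusted p of 0.0974 with an estimated correlation, and cyclin Ccnd2 fell by 1.67 (SE 0.05). Immediate early and heat shock genes, of which 9 of 15 were lower and 1 higher, gave 0.00199 and an adjusted p of 0.0866 with an estimated correlation, with Zfp36 (−1.66, SE 0.10) and Junb (−0.91, SE 0.06) lower. Mitochondrially encoded mRNAs, of which 7 of 12 were higher and 1 lower, gave 0.00289 and an adjusted p of 0.371 with an estimated correlation, with mt-Cytb (1.14, SE 0.03) and mt-Nd4 (0.47, SE 0.03) higher. Ribosomal protein mRNAs, of which 76 of 88 were lower and 3 higher (median −0.44), gave 7.13e-20 and an adjusted p of 0.176 with an estimated correlation, with Rpl26 (−0.64, SE 0.03) and Rpl3 (−0.60, SE 0.03) lower.

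The other lists were not called by camera in EBs. Primitive streak genes were 8 higher and 4 lower of 16 (adjusted p = 0.237), with Lefty2 at 26.2 ± 1.67 CPM in KD and 5.95 ± 1.04 CPM in WT EBs. Definitive endoderm and gut genes were 6 higher and 5 lower of 16 (adjusted p = 0.835, mean and test of opposite sign), with the carboxypeptidase gene Cpm lower (−0.70, SE 0.04). Neuroectoderm genes were 7 higher and 5 lower of 20 (0.954, median and mean below 0 with a positive test direction), with Ncam1 higher (1.12, SE 0.08). Surface ectoderm genes were 3 higher and 7 lower of 13 (0.112, median and mean of opposite sign), with Krt18 lower (−0.77, SE 0.03), and were called with DESeq2 (0.00266). Trophoblast genes were 3 higher and 7 lower of 12 (0.672), with Peg10 higher (0.94, SE 0.03). Germline genes were 6 higher and 2 lower of 17 (0.605), with Nanos3 higher (3.54, SE 0.69). Interferon response genes were 3 higher and 7 lower of 19 (0.114), with Bst2 lower (−1.36, SE 0.06). WNT targets were 9 higher and 4 lower of 16 (0.401), with Cdx2 higher (1.01, SE 0.06). LIF and STAT3 targets were 6 higher and 6 lower of 16 (0.255), with the kinase gene Pim3 lower (−1.25, SE 0.04). ERK targets were 8 higher and 5 lower of 17 (0.401), with Fos lower (−2.26, SE 0.10). TGF-beta, NODAL and BMP targets were 8 higher and 6 lower of 17 (0.179). Integrated stress response genes were 6 higher and 9 lower of 20 (0.364), with the serine synthesis gene Phgdh lower (−0.72, SE 0.04). Replication-dependent histones, which a poly-T selection captures poorly, were 5 higher and 5 lower of 27 (0.954, mean and test of opposite sign), with Hist1h1c lower (−0.67, SE 0.10). Core pluripotency (adjusted p = 0.00141) and TGF-beta, NODAL and BMP targets (0.0124) were called in the fit of all 12 libraries, and cell cycle genes were not (0.0650). Adjusted over the list alone, the counts of the 31 EB lists differed by at most 1 gene per direction from those over all genes.

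**Figure D3:**
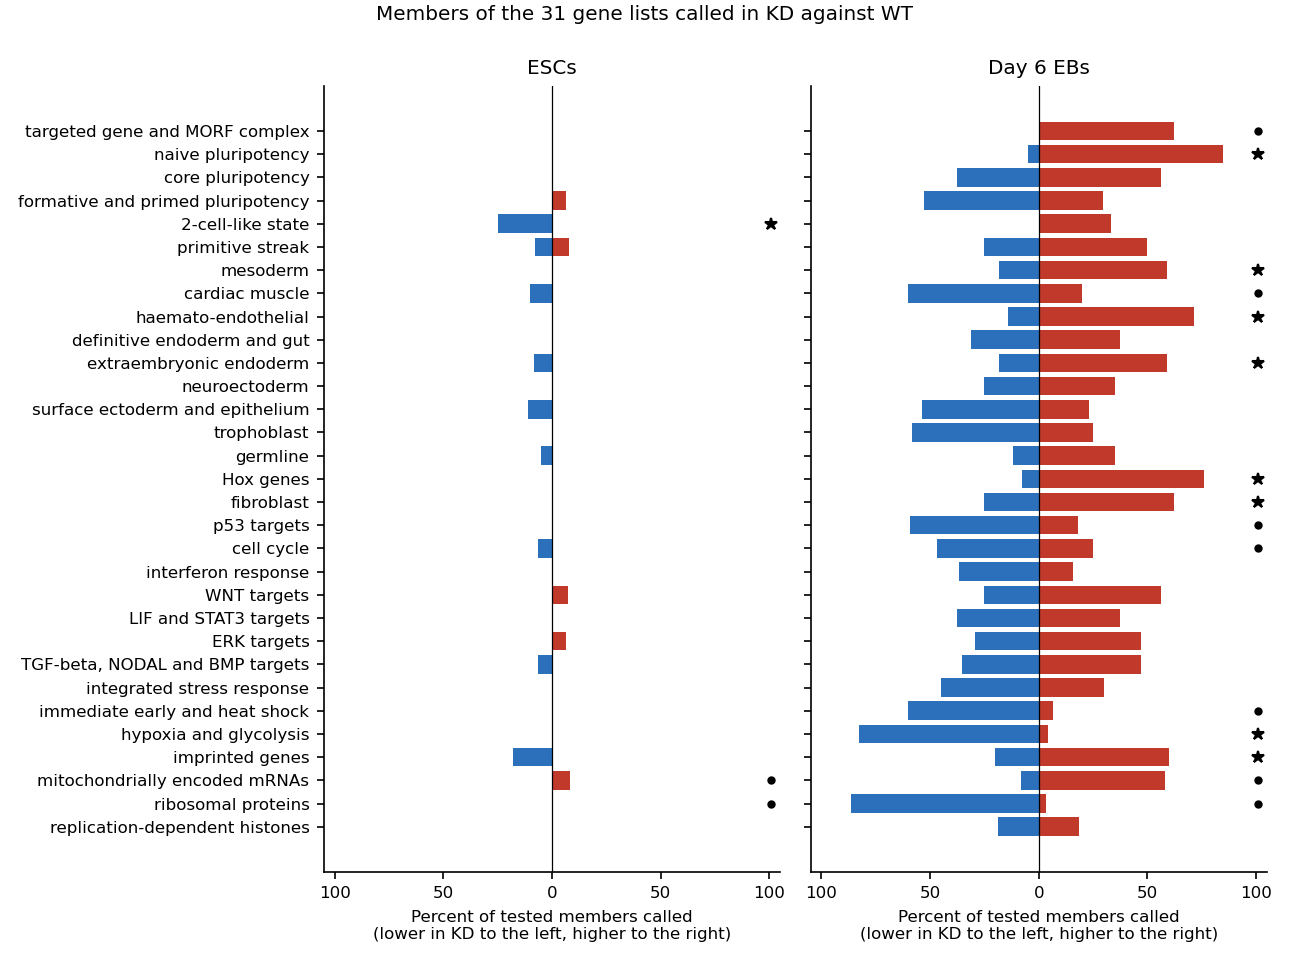
Percent of the tested members of each of the 31 gene lists that were called higher (red, to the right) or lower (blue, to the left) in KD than in WT cells, in ESCs and in day 6 EBs. A star marks a list with a camera adjusted p under 0.05 that held with an estimated correlation, and a dot one that did not hold. In EBs naive pluripotency and Hox genes lie mainly to the right, with 17 of 20 and 29 of 38 members higher, and hypoxia and glycolysis genes to the left, with 19 of 23 lower.

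By edgeR, 9667 of 17355 tested genes changed in EBs, 4865 higher and 4802 lower, and 2402 of them (1234 higher, 1168 lower) by a log2 fold change of at least 1. With any 1 EB library left out the count lay between 8923 and 9230, and 7636 genes were called in each of the 6 fits. In the fit of all 12 libraries it was 6650, with 3807 higher and 2843 lower (57.2% higher against 50.3%). The biological coefficient of variation was 0.0833 in EBs and 0.180 in ESCs, so the counts of the 2 stages were reached at different precision.

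With all libraries included, the KD calls of the 2 stages overlapped by more than independent lists would, by a test that takes genes as independent. Among 14670 genes tested in both stages, 13 genes were higher in both against 7.14 expected (odds ratio 2.72, 95% interval 1.14 to 6.52, two-sided Fisher's exact p = 0.0138), including Myc, Sp5, Nefm and Vegfc. Another 29 were lower in both against 18.5 expected (odds ratio 2.09, 95% interval 1.22 to 3.56, Fisher's exact p = 0.00495), including Phlda2, Slc22a18, Cdkn1c, Celsr2, Amn, Myl4 and Krt19. The ESC calls of Myc, Sp5, Nefm, Vegfc, Amn, Myl4 and Krt19 were lost with some ESC libraries left out, as given above. That of Cdkn1c (edgeR adjusted p = 0.0349) was not made in every such fit, unlike those of Phlda2, Slc22a18 and Celsr2. Opposite calls numbered 5 (Fisher's exact p = 0.383) and 14 (Fisher's exact p = 0.395), and Dnmt3b and Lefty2 were among them. Across these genes, which are not independent replicates, log2 fold changes of the stages had Pearson's r of 0.13 and a covariance of 0.0420. The shared calls numbered 42, and 14, 710 and 123 without ESC WT replicates 1, 2 and 3, and 3, 3 and 4 without ESC KD replicates 1, 2 and 3. No expected number was computed for the fits with a library left out, so an excess in them was not tested.

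**Figure D4:**
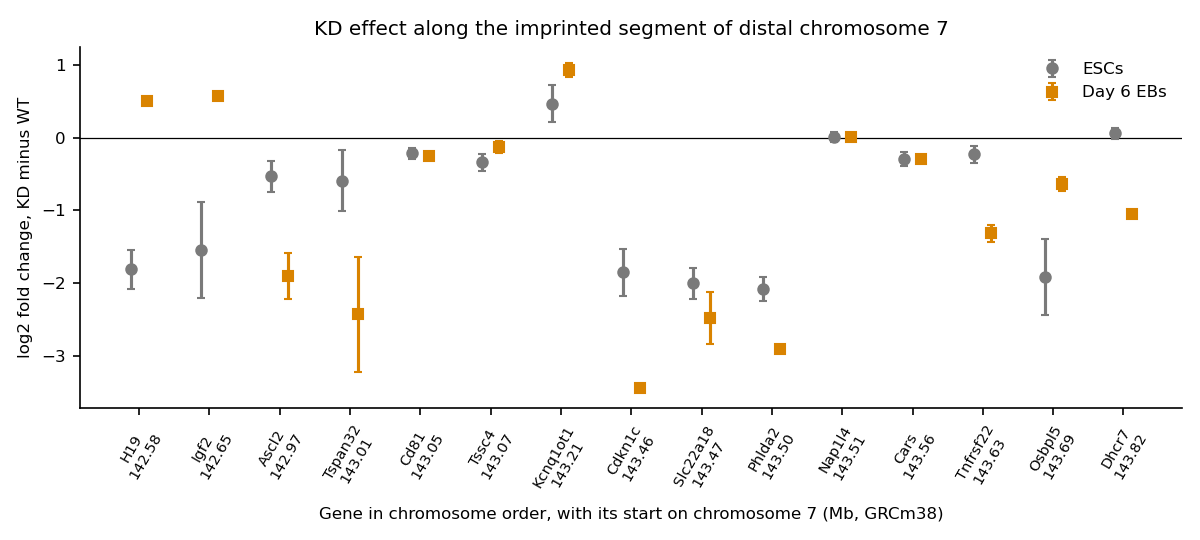
Log2 fold change of KD against WT with its SE for selected tested genes of the imprinted segment of distal chromosome 7, in chromosome order, with starts in Mb (GRCm38), for ESCs (grey circles) and day 6 EBs (orange squares). Cdkn1c, Slc22a18 and Phlda2 were lower at both stages, at −1.85, −2.004 and −2.08 in ESCs and −3.45, −2.48 and −2.91 in EBs, while their neighbour Nap1l4 lay at 0.01 in both. Ascl2, Tspan32, Tnfrsf22 and Dhcr7, among others, were also lower in KD EBs (these 4 from −2.43 to −1.05), and H19, Igf2 and Kcnq1ot1 were higher. The ESC call of Cdkn1c was not made in every fit with 1 ESC library left out.

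A test of the difference between stages asked whether the KD effect changed with differentiation. It was higher in EBs than in ESCs for 2430 genes and lower for 1940 of 18975 (4370 called, 55.6% of them higher). With library size only these were 1457 higher and 2676 lower (35.3% higher), so the split by direction depends on the scaling. It also depends on single ESC libraries, with 47.2% higher (2126 higher, 2375 lower) without ESC WT replicate 1 and 50.1% to 51.9% without any other of them. The median difference over all genes was 0.03 with the main scaling and −0.13 with library size only. The KD effect was higher in EBs for naive pluripotency genes (14 higher and 1 lower of 20, median difference 1.35, camera adjusted p = 2.69e-26, and adjusted p = 0.00128 with an estimated correlation). It was lower for hypoxia and glycolysis genes (16 lower and 1 higher of 23, median −0.52, camera adjusted p = 5.52e-11, and adjusted p = 0.0338 with an estimated correlation).

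From ESCs to EBs, WT cells lost naive and core pluripotency transcripts and gained those of mesoderm, endoderm and extraembryonic lineages. All 20 naive genes fell (median −4.98, camera adjusted p = 3.88e-27), such as Klf2 (562 ± 4.17 to 3.95 ± 0.503 CPM) and Tfcp2l1 (log2 fold change −4.82, SE 0.07), and 12 of 16 core genes fell, such as Tdgf1 (−5.96, SE 0.07). Of 22 mesoderm genes 19 rose and 1 fell (camera adjusted p = 4.33e-12), with Hand1 going from 0.411 ± 0.219 to 770 ± 5.62 CPM (10.82, SE 0.17). The endodermal Gata6 (8.06, SE 0.16) and Dab2 (8.13, SE 0.16), Col1a1 (7.44, SE 0.15), the keratin Krt8 (6.03, SE 0.09), Myl3 (6.35, SE 0.36), Kdr (5.82, SE 0.22), Hoxd8 (5.86, SE 0.34), Cdkn1c (4.95, SE 0.13) and Kat6a (1.94, SE 0.07) rose. Of 25 imprinted genes 24 rose and 1 fell, with Peg10 at 6.99 (SE 0.09), and 88 of 89 ribosomal protein mRNAs fell, with Rpl39l at −7.86 (SE 0.12). Others that fell were Cdx1 (−7.74, SE 0.17), Gm21761 (−5.11, SE 0.33), Oas1a (−4.90, SE 0.13), Hspb1 (−4.57, SE 0.08), Tex19.1 (−4.24, SE 0.16), Dnmt3l (−3.70, SE 0.07), Tubb3 (−3.49, SE 0.12), Etv5 (−3.39, SE 0.11), Asns (−3.34, SE 0.06), Aldoa (−2.89, SE 0.07), Hist1h2bc (−2.71, SE 0.22), Sesn2 (−1.41, SE 0.06) and mt-Cytb (−1.22, SE 0.06). The edgeR adjusted p of these genes ran from 7.75e-18 for Tdgf1 to 1.38e-08 for Hist1h2bc.

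In WT cells 15133 of 18975 genes changed with stage (8061 higher, 7072 lower), and in KD cells 15142 (8055 higher, 7087 lower). With library size only the WT split was 9876 higher and 5272 lower (65.2% against 53.3% higher), as that scaling moved the median of all genes by 0.53 on the log2 scale in WT and 0.37 in KD cells.

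Of the 500 genes with the largest rise from ESCs to EBs, 243 were higher and 77 lower in KD EBs (median 0.47, camera adjusted p = 2.20e-13, and adjusted p = 0.00406 with an estimated correlation). Of the 500 with the largest fall, only 89 passed the filter in EBs, and 47 of these were higher and 9 lower (median 1.00, camera adjusted p = 1.02e-05, and adjusted p = 0.00669 with an estimated correlation). That median lay between 1.33 and 1.68 with any 1 of the 12 libraries left out, the highest without EB WT replicate 1, and was 2.26 with 200 genes per set and 0.59 at a mean CPM of at least 1. A gene passed the filter when it was expressed in WT or in KD EBs, so the KD effect itself had a part in which genes were tested. Without a filter, 339 of the 500 were tested and the adjusted p rose to 0.0232 (median 1.02), and with DESeq2 and 363 tested genes the call was not made (adjusted p = 0.0856). In ESCs 495 of the falling genes were tested, of which 1 was higher and 13 lower (median −0.18, camera adjusted p = 3.69e-05, lost at an adjusted p of 0.157 with an estimated correlation, and a median of −0.05 with library size only). Only 25 of the rising genes were tested in ESCs (median −0.12, camera adjusted p = 0.831), and the sign of that median changed with the setting.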

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

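All tests of explanations in this part, the splits of the libraries included, were chosen or had their expectation written after the results they address were seen. The KD effect differed between EBs and ESCs for 4370 genes. Of 100 splits drawn from the 200 possible, 2 gave as many, the real one included, and the highest other gave 5731. That split exchanged the ESC labels, and the 9 splits that retained the EB groups, the real one included, gave 2802 to 5731, while the 91 that mixed them gave at most 3. The count of a split thus follows the EB groups, so these splits cannot tell whether chance in the ESC groups accounts for a difference between stages.

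For the comparisons within a stage, 10 splits of 6 libraries are too few for a share under 0.05. The real split, 1 of the 10 in each, gave 97 genes in ESCs against 1 in the highest other split, and 9667 in EBs against 1. From ESCs to EBs it gave 15133 genes in WT cells and 15142 in KD cells against 0 in the highest other split.

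A test of the difference between stages marked further lists, each given as the median difference in log2 fold change. The KD effect was higher in EBs for the 2-cell-like state (3.90, camera adjusted p = 0.0180 with an estimated correlation), haemato-endothelial (2.03), naive pluripotency (1.35), Hox (1.28), core pluripotency (0.61), the MORF complex (0.58), imprinted genes (0.575) and extraembryonic endoderm (0.57). It was lower for cardiac muscle (−0.89), immediate early and heat shock (−0.75), hypoxia and glycolysis (−0.52) and p53 targets (−0.27). For the 2-cell-like state the difference came with the fall in KD ESCs given above. Within EBs only 6 of its genes were tested, with a median of 0.68 and no call (camera adjusted p = 0.605). With an estimated correlation the camera adjusted p was 0.00128 for naive pluripotency and 0.0338 for haemato-endothelial, Hox, core pluripotency, extraembryonic endoderm and hypoxia and glycolysis. It was 0.290 for the MORF complex, 0.180 for cardiac muscle, 0.247 for imprinted genes and 0.0727 for p53 targets and for immediate early and heat shock, so these calls were lost.

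The largest single differences under the naming rule lay mostly in genes with a group of libraries near 0, so levels are given in place of folds. In WT and KD EBs, Col3a1 stood at 9.46 and 722 CPM (edgeR adjusted p = 0.0177), Lum at 0.585 and 34.5 (0.0158), Irs4 at 7.03 and 36.2 (0.00307), Ednra at 7.36 and 19.6 (7.14e-04) and Rbm46 at 6.23 and 12.4 (0.0394), with ESC levels of at most 0.238 CPM. Nog stood at 17.7 and 8.19 CPM (4.34e-04), Col9a1 at 17.9 and 8.82 (0.0153), Amer3 at 32.9 and 5.14 (0.0441), Bmper at 17.4 and 13.1 (0.02502) and Aff2 at 7.17 and 13.9 (0.00751), with ESC levels of at most 0.372 CPM. Aff2 was therefore higher in KD EBs than in WT EBs, and its difference between stages came from its ESC levels of 0 in WT and 0.221 CPM in KD cells. In WT and KD ESCs, Spic stood at 15.4 and 12.9 CPM (3.97e-05) and Bhmt at 8.63 and 9.71 (0.0439), with EB levels of at most 0.383 CPM. Only Irs4, Ednra, Nog and Spic were called in each setting tried. Of the 12 fits with 1 library left out, Rbm46 lost its call in 10, Amer3 and Bhmt in 9, Bmper in 2 and Col3a1, Lum and Col9a1 in 1. With the replicate block the calls of Col3a1, Rbm46, Amer3 and Bhmt were lost, and with voom and sample weights those of Col9a1, Bmper, Aff2 and Bhmt. Dnmt3b (edgeR adjusted p = 9.24e-07), higher in KD ESCs and lower in KD EBs, and Lefty2 (3.59e-08), with the opposite pattern, also differed between stages.

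Cdkn1c, Phlda2 and Slc22a18, imprinted neighbours on chromosome 7, were lower in KD cells at both stages. In ESCs Phlda2 and Slc22a18 were called in every fit with 1 ESC library left out, and Cdkn1c (edgeR adjusted p = 0.0349) was not. A loss of copies of the segment would lower its other genes by about 1, and the 24 others tested around them had a median of −0.39 averaged over both stages (95% bootstrap interval −0.65 to −0.18, with −0.55 in ESCs and −0.30 in EBs). These 24 included H19 and Igf2, which stood lower in ESCs and higher in EBs. The median of the 24 thus does not follow copies alone and cannot decide. Nap1l4, a neighbour of Phlda2, stood at 0.01 in both stages (SE 0.07 in ESCs and 0.04 in EBs). This argues against a loss that included Nap1l4, in all cells or in enough of them to give the fall of Phlda2. In KD EBs Ascl2 (−1.91), Tspan32 (−2.43, from only 0.473 CPM), Tnfrsf22 (−1.32) and Dhcr7 (−1.05) were lower. Osbpl5 (−0.64), Cars (−0.30) and Cd81 (−0.25) were lower there too (edgeR adjusted p of these genes from 1.31e-19 to 0.00983). None of these genes passed in ESCs. H19 and Igf2 of the same segment, chosen after their values were seen, stood at −1.81 and −1.54 in ESCs and rose by 0.51 and 0.57 in EBs (edgeR adjusted p = 0.0196 and 0.209 in ESCs, 5.36e-16 and 1.08e-19 in EBs). The ESC call of H19 was not made in every fit with 1 ESC library left out. A loss limited to parts of the segment without Nap1l4 stays open, in all or in part of the cells. A second active copy of Kcnq1ot1, the RNA that silences these genes in cis, may be a candidate explanation, and it rose by 0.93 in EBs (edgeR adjusted p = 6.58e-10) but stood at 0.47 in ESCs (0.314). Counts without strand do not separate this RNA from its host Kcnq1, and no allele was measured. Neither this explanation nor a loss of part of the segment was decided. An effect of the KD itself is not separated from a difference between the cell populations used as WT and KD.

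Counts on Y-linked genes stood almost only in the WT EB libraries, with 282 for Eif2s3y, 204 for Ddx3y and 91 for Uty, against 0, 0 and 7 in the other 9 libraries. Each of the 3 WT EB libraries held at least 90, 61 and 18 of these. At the rate of WT EBs, reads of the X-linked copies would have brought 862.4 counts to the other 9 libraries against the 7 found. This excludes them as the cause if the rate was equal in all libraries. A rate particular to WT EBs was not tested. The lower Poisson bound of 805 covers counting error only, with each mate counted and PCR copies not told apart. E14 is generally known as a male line, so the near absence of these counts in 9 libraries is the unusual side. Cells with a Y chromosome in the WT EB cultures alone may be a source. Kdm5d had only 1 count there and Usp9y 0, but no male reference library gave their due levels, so these counts do not decide it. The Y-linked counts were also few beside those of the X-linked copies in WT EBs, at 282 against 14892 for Eif2s3x and 204 against 64211 for Ddx3x. These counts do not tell a small source from WT EBs of another cell population than KD EBs and WT ESCs, and both stay open. Another population would bear on all 9667 EB calls, the 15133 calls between stages in WT cells and the 4370 of the difference.

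ESC WT replicate 2 stood apart from the other ESC libraries. Its depth of 31.4 M lay between the 29.0 and 37.8 M of the other WT libraries, which excludes a lower depth. The deviation of its genes correlated with gene length and GC content (Spearman's rho −0.28 and 0.22), as did that of WT replicate 1 in the opposite direction (0.26 and −0.25), and with these trends removed the SD of its log2 deviation was still 0.366, against at most 0.276 in the other WT ESC libraries, so the trends could not be the whole cause. It also had the fewest genes with a count of the 12 libraries (20021). Its 10 most counted genes held 7.08% of its counts, against 5.66% and 5.59% in WT replicates 1 and 3. No batch label was used here, and a difference of that library or culture stays open and untested.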

How the results depend on the processing

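Halved counts and voom with sample weights were chosen after seeing the data. The causes of the changes below were not tested, except that fewer libraries or genes enter some settings by construction. Genes changed in ESCs numbered 97, and 36 with library size only, 33 at a log2 fold change of at least 1, 909 with DESeq2, 1032 with voom and sample weights, 1769 without a filter, 1999 in the fit of all 12 libraries, and 8 to 1557 with 1 library left out. Shared calls numbered 42, and 16, 390, 466 and 744 with library size only, DESeq2, voom and no filter, and 3 to 710 with 1 library left out. At a log2 fold change of at least 1 there were 2402 genes in EBs and 1620 for the difference. The falling set in ESCs had an adjusted p of 0.157 (median −0.18) with an estimated correlation, the falling set in EBs 0.0856 (0.99) with DESeq2, and the rising set in ESCs 0.00549 (−1.17) with 200 genes per set, of which 6 were tested. The median of the rising set in ESCs changed sign in some settings, such as library size only, without a call in these. The other counts and sets retained their side of the threshold, and no called result reversed. Of the list results in EBs 499 stayed, 8 lost and 18 gained a call, and in ESCs 514, 5 and 8. Of the 18 gained in EBs, 14 came with fry, which tests a list against no change and not against the other genes. Of the named genes 891 results stayed and 5 lost the call in EBs, and in ESCs 368 stayed, 70 lost and 9 gained it. Named genes of the difference retained 195 and lost 45. Library size only moved the median of all genes by 0.11 in ESCs and −0.16 for the difference.

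Replicate numbers did not pair the libraries, as the deviations of same-numbered libraries within a stage correlated between −0.025 and 0.026 over 6 pairs. With the number as a replicate block 266 genes were called in ESCs and 124 were shared, 9655 in EBs, 4023 for the difference, and 14922 and 14910 from ESCs to EBs in WT and KD cells.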

Other observations

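The genes and groups of this part were chosen after their values were seen, and the trend below was tested on the same data. The rise of Hox transcripts in KD EBs went with position in the clusters. Of 12 genes of paralogue groups 1 to 4, 3 rose and 3 fell (median log2 fold change 0.18, from −1.18 to 1.90). All 11 genes of groups 5 to 8 rose (median 1.86), and so did all 15 of groups 9 to 13 (median 3.84, from 0.72 to 7.42). Across these 38 genes, which are not independent, Spearman's rho between group number and log2 fold change was 0.823 and Pearson's r 0.800 (two-sided permutation p = 1e-05 for rho, the smallest that the draws can give). A gene could pass the filter through the KD EBs alone, and levels did not enter this trend. Whether it follows low levels in WT EBs was not tested. Pitx1 and Tbx4, transcription factors of the hindlimb field, rose from 22.6 ± 1.23 to 250.2 ± 11.1 CPM and from 6.21 ± 0.950 to 76.8 ± 0.0794 CPM (log2 fold changes 3.47 and 3.63, edgeR adjusted p = 8.35e-31 and 4.73e-25).

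Pluripotency genes did not move as a block in KD EBs. Nr0b1 (0.0974 to 5.68 CPM), Prdm14 (0.183 to 2.60) and Dppa2 (0.999 to 9.85) were higher, with edgeR adjusted p of 4.44e-12, 2.34e-09 and 3.71e-06, and Sox2 went from 46.2 ± 0.961 to 88.4 ± 7.15 CPM (adjusted p = 3.63e-15). Nanog stood at 55.6 ± 3.70 CPM in WT and 52.1 ± 1.83 CPM in KD EBs (log2 fold change −0.10, SE 0.06, adjusted p = 0.182). Endothelial Cdh5 and Tie1 rose by 4.08 and 3.85 on the log2 scale, and the atrial light chain Myl7 fell by 3.03 and the neural factor Sox1 fell by 2.38. Imprinted genes outside chromosome 7 went both ways. Nnat rose by 1.93 (SE 0.07), while Grb10 fell by 1.43 (SE 0.07) in EBs and Plagl1 fell by 1.55 (SE 0.27) in ESCs and by 1.53 (SE 0.48) in EBs, where its level was 1.23 CPM in WT and 0.424 CPM in KD cells. On chromosome 7, H19 was lower in KD ESCs (5.87 to 1.67 CPM, edgeR adjusted p = 0.0196) and higher in KD EBs (1235 to 1756 CPM, edgeR adjusted p = 5.36e-16). The ESC calls of Plagl1 (edgeR adjusted p = 0.0364) and H19 were not made in every fit with 1 ESC library left out.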
